A study of Homo sapiens with 10 samples.

How the data were processed

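The analysis used 3 peak lists: H3K4me3 ChIP-seq of primary human melanocytes transfected with siMITF, the same with siSCR, and MAX ChIP-seq of COL0829 cells. Per the labels' protocols, the melanocytes were incubated for 72 h with the siRNA, their libraries were made with 18 PCR cycles and read as 75 bp single-end reads, and the COL0829 library was read as 50 bp single-end reads. The submitters' processing notes name Bowtie2, MACS2 and Cuffdiff, and hg19 as the genome build, with no versions. Peaks were called per sample, since each list belongs to 1 library.

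The deposited lists have no header, and their columns follow the layout MACS2 writes. The authors' fold column is a linear ratio of pileup over local background, with a pseudocount. The authors' −log10 columns hold the p and q value of each peak. The deposited score column is about 10 times the −log10 q, rounded down, and was not used beyond that check. The other deposited column, in the MAX list alone, is the distance from the peak start to the summit in bases. The H3K4me3 lists are in the broad layout, where MACS2 averages each value over the region. Peak names show that duplicates had been removed and that the H3K4me3 libraries came from different lanes of the same flow cell. The names in the MAX list spell the cell line with digits exchanged, and the siSCR list's name uses another control abbreviation than its label. Groups were taken from the labels.

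Peaks on chromosomes 1 to 22 and X were kept. A peak counted as shared when at least 1 base overlapped a peak of the other list, and a MAX peak counted as inside H3K4me3 when its summit did. Shares have exact Clopper-Pearson 95% intervals, and the difference between peaks with and without MAX has a Newcombe interval. Chance overlap came from 1000 circular shifts of all peaks along each chromosome, with 200 shifts for distances to H3K4me3. The overlap shifts ran up to the end of each chromosome's last peak and left out no stretch where peaks cannot be called. The shifted means may therefore understate chance overlap. Windows of 10 Mb were kept with at least 20 siSCR peaks and at least 5 MAX summits outside H3K4me3. PCR reads are not independent molecules and neighbouring peaks are not independent of one another, so intervals and limits cover counting error only. With 1 library per arm no p-value was computed, and fold and q were mainly used to rank or filter peaks within a list. Between the lists, the background solved from fold and p was compared, and shared siSCR peaks were matched with their best siMITF −log10 q.

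For each MAX peak, the summit pileup and local background were solved from the fold and p, taking fold as pileup plus 1 over background plus 1 and p as the Poisson tail above the pileup. All 6403 peaks gave a whole-number pileup within a tolerance of 0.001 in −log10 p. The lowest background, 0.485 reads, is the genome-wide floor, at which 741 peaks (11.6%) lie. For H3K4me3 the same solution is approximate, since the values are averages, and it was used over shared peaks wider than 1500 bp. Tested on simulated data, the solution recovered the pileup of 100% of 1906 narrow peaks, and a planted background ratio of 0.5 came back as 0.513 over 1000 broad peaks. The simulated broad peaks kept the same enrichment at each depth. Whether a change in signal alone would move the ratio was therefore not tested.

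No hg19 annotation or sequence was used here. Promoter assignment, E-box and gene list results that had been planned were therefore not run, and the named regions follow the rule set for that case before the data were examined: the 5 peaks of highest fold missing from the other H3K4me3 list, the 5 MAX peaks of highest fold in all and outside both H3K4me3 lists, and the 5 widest H3K4me3 peaks of each arm. Regions named beyond that rule were chosen after their values were seen. These are the chromosome 6 stretch, the siSCR peaks with 4 MAX summits, the siSCR peaks with the smallest covered shares and the MAX peak of highest background.

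Alternatives planned before the data were examined were a 50% minimum overlap, a −log10 q of at least 5, equal numbers of top peaks from each list, merging of peaks within 1 kb, whole MAX peaks in place of summits, and averages over quintiles of width or fold. Alternatives and thresholds chosen after the data were seen were a −log10 q of 20, a siMITF peak within 1 kb, MAX peaks with 20 or more reads, MAX peaks with background under 10 times the floor, 30 strata of fold and width, fold quintiles 1 to 3 alone, the position of MAX summits and its stricter lists, and the splits by list median, decile, pileup and chromosome. RNA-seq and input samples were not analysed here. The work used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.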

Results

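The series set the binding of MITF, the melanocyte lineage transcription factor, against that of MYC-MAX, a related pair of E-box binding factors, in melanoma and melanocytes. It holds 10 samples, of which 3 were analysed here as peak lists. In primary human melanocytes, H3K4me3, a histone mark of active promoters, was mapped by ChIP-seq 72 h after transfection with siRNA against MITF (siMITF) or with a control siRNA (siSCR). MAX was mapped by ChIP-seq in COL0829, a melanoma cell line. The 4 RNA-seq samples and the 3 input samples were not analysed here, and whether MITF was depleted was not checked. Each peak list came from 1 library, so no value has a replicate error, and the 95% intervals (exact Clopper-Pearson unless another method is named) cover counting error only.

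On chromosomes 1 to 22 and X, the siSCR list held 33672 H3K4me3 peaks over 58.1 Mb and the siMITF list 24431 peaks over 47.1 Mb. The siSCR peaks had a median width of 1204 bp and a median fold enrichment over background of 6.21. The siMITF peaks had a median width of 1536 bp and a median fold of 8.50. The MAX list held 6403 narrow peaks over 1.67 Mb, with a median width of 225 bp and a median fold of 5.80. Folds and −log10 q values are those of the authors' peak caller. They are used within a list, except for the implied background below and the best siMITF −log10 q of shared siSCR peaks. Read totals per library were not used here. The background implied by fold and p over shared peaks wider than 1500 bp had a median of 4.96 reads in siSCR and 2.45 reads in siMITF, a ratio of 0.494.

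The first comparison asked where promoter-type chromatin differed between melanocytes with and without MITF siRNA. Most H3K4me3 regions were present in both arms, and the difference in list length came from weak siSCR peaks. Of the siMITF peaks, 96.1% (95.8 to 96.3) overlapped a siSCR peak, and of the siSCR peaks, 69.3% (68.8 to 69.8) overlapped a siMITF peak. Random circular shifts of the peaks along each chromosome gave means of 4.50% and 3.28%. The shared bases came to 43.4 Mb, or 74.6% of the bases in the siSCR list.

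Presence in the other arm followed the strength of the peak. In siSCR, 18.2% (16.9 to 19.5) of the peaks in the lowest decile of fold had a siMITF peak, 48.0% (46.3 to 49.7) in decile 4 and 96.6% (96.0 to 97.2) in decile 6. From decile 7 upwards, at folds of 9.54 or more, each decile had at least 99.7%. In siMITF, 77.9% (76.2 to 79.5) of the lowest decile had a siSCR peak, and from decile 6 upwards all peaks did. The 10351 siSCR peaks without a siMITF peak had a median fold of 3.31 and a median width of 534 bp, against 11.7 and 1821 bp for shared peaks. The 954 siMITF peaks without a siSCR peak had a median fold of 3.29 and a median width of 418.5 bp.

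**Figure D1:**
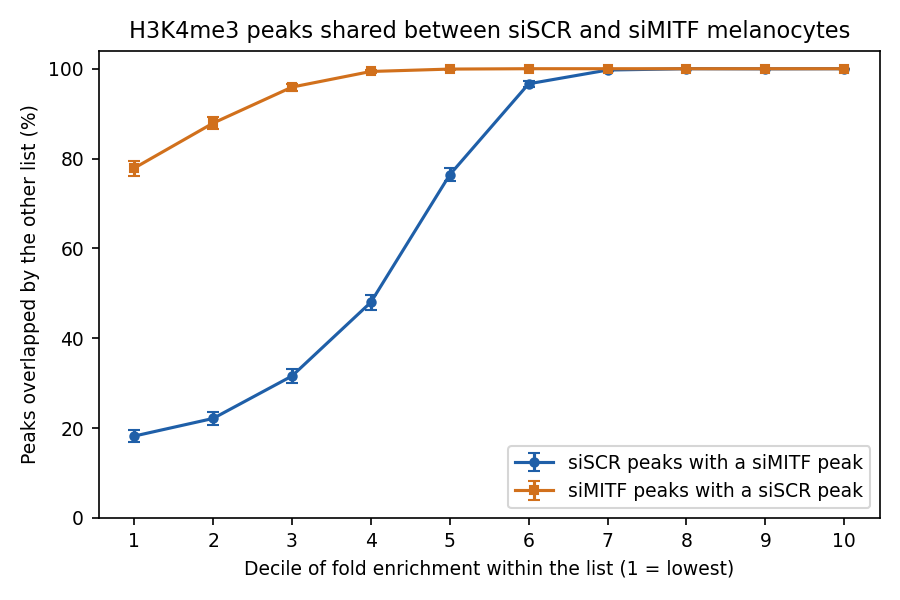
Percent of H3K4me3 peaks overlapped by a peak of the other arm (y axis) by decile of fold enrichment within each list (x axis, 1 is lowest), for siSCR peaks (blue circles) and siMITF peaks (orange squares), 1 library per arm. Error bars are exact 95% intervals for counting error; the siSCR line climbs from 18.2% in decile 1 to 96.6% in decile 6, and the siMITF line starts at 77.9%.

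Strong peaks confined to the siSCR list were few. Among the 16836 siSCR peaks at or above the list's median −log10 q of 14.8, 103 (0.612%) had no siMITF peak, and none of the 103 had one within 1 kb. Of the 12216 siMITF peaks at or above that list's median −log10 q of 18.3, 0 lacked a siSCR peak, which allows a share of up to 0.0246% by the limit of 3 counts. A threshold of −log10 q of 20, chosen after the values were seen, left 39 of 15569 siSCR peaks without a siMITF peak and 0 of 11796 siMITF peaks without a siSCR peak. The implied background of siMITF was 0.494 times that of siSCR, so a given −log10 q need not mark equally strong peaks in both lists. These counts therefore do not show a one-sided loss of strong peaks.

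Positions are 1-based hg19 coordinates, and the regions were not assigned to genes here. The siSCR peaks of highest fold with no siMITF peak within 1 kb began with a 4805 bp region on chromosome 15, 86265511 to 86270315, with a fold of 16.3 and a −log10 q of 85.4. A 3724 bp region on chromosome 16, 19773983 to 19777706, had a fold of 12.3 and a −log10 q of 58.2. Chromosome 5 held a region at 59835359 to 59838547, with a fold of 11.4, and another at 74907065 to 74907941, with a fold of 11.1. A 3700 bp region on chromosome 17, 79608850 to 79612549, had a fold of 11.4. None of these 5 regions contained a MAX summit.

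The siMITF peaks of highest fold with no siSCR peak within 1 kb were weaker within their own list. They lay on chromosome 21 at 45705521 to 45705959, with a fold of 6.90, and on chromosome 11 at 15135985 to 15140901, with a fold of 6.82. Chromosome 11 held 2 more, at 43033988 to 43035117 with a fold of 5.99 and at 64409248 to 64411312 with a fold of 5.39. Chromosome 5 held a region at 53751523 to 53754261, with a fold of 5.94. None of these contained a MAX summit.

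Among the 103 siSCR peaks at or above the median −log10 q without a siMITF peak within 1 kb, 1 pair lay within 500 kb. Random sets of 103 peaks were drawn 1000 times from the 16836 siSCR peaks at or above that median. They held a mean of 3.565 pairs (0 to 8 over the central 95% of sets). The pair, chosen after its values were seen, lay on chromosome 6 at 4344347 to 4347488 (fold 9.67) and at 4610222 to 4613723 (fold 10.2), 263 kb apart. A siSCR peak nearby, at 4647320 to 4648314 with a fold of 7.21, had a siMITF counterpart at 4647321 to 4648043.

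**Figure D2:**
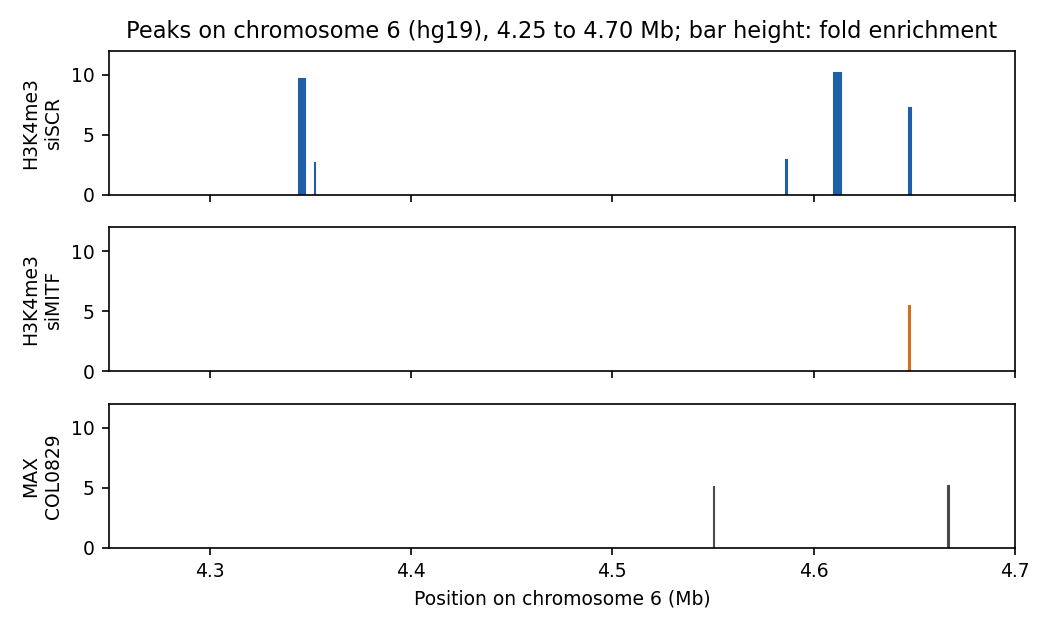
H3K4me3 peaks of siSCR (blue) and siMITF (orange) melanocytes and MAX peaks of COL0829 cells (grey) on chromosome 6 of hg19 (x axis, Mb), with bar height giving the fold enrichment in each list (y axis) and bars drawn with a thin outline so that narrow peaks stay visible. The stretch holds 5 siSCR, 1 siMITF and 2 MAX peaks; the siSCR peaks with folds of 9.67 and 10.2 have no siMITF peak.

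The widest H3K4me3 regions were present in both arms and were covered to different extents in the other arm. The widest siSCR peak, 40721 bp on chromosome 9 at 15846077 to 15886797, was 69.0% covered by siMITF peaks. A 35653 bp peak on chromosome 4 at 15002265 to 15037917 was 87.1% covered, and a 35312 bp peak on chromosome 2 at 37519685 to 37554996 was 76.0% covered. A 29598 bp peak on chromosome 3 at 41239871 to 41269468 was 83.7% covered. The fifth, 28025 bp on chromosome 11 at 65183521 to 65211545, was 100% covered and contained 1 MAX summit.

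The widest siMITF peak, 28900 bp at 65182844 to 65211743, lay over that chromosome 11 region. It was followed by 27135 bp on chromosome 3 at 69984902 to 70012036 and by 26251 bp on chromosome 2 at 37528654 to 37554904. Chromosome 2 also held a 25654 bp peak at 223146737 to 223172390 and a 25028 bp peak at 145257963 to 145282990. Of the 100 widest siSCR peaks, 52 overlapped one of the 100 widest siMITF peaks, and 0 of them lacked a siMITF peak of any width.

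The next comparison asked how MAX binding in the melanoma line lay relative to the melanocyte H3K4me3 landscape, as a feature of the local chromatin. About equal numbers of MAX summits lay inside and outside siSCR H3K4me3. The share inside was 50.1% (48.9 to 51.3; 3208 of 6403), 22.2 times the mean of 2.25% over shifted positions. The share inside siMITF H3K4me3 was 44.9% (43.6 to 46.1, 2872 of 6403), 24.4 times its shifted mean of 1.84%. The shifts left out no stretch where peaks cannot be called, so both ratios may be too high. Both arms marked 43.9% of the summits, siSCR alone 6.23%, siMITF alone 0.984% and neither 48.9%.

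MAX summits lay toward the centre of the H3K4me3 regions. Of the 3208 summits inside siSCR peaks, 43.2% (41.5 to 44.9) fell in the central stretch that holds 33.3% of the peak's width. The outermost 10% of the width at either end held 7.29% together, against 20% for even spacing. Of the siSCR peaks, 8.59% (8.29 to 8.89) contained a MAX summit, rising from 2.30% in the lowest quintile of fold to 18.8% in the highest. Strong peaks were also wider, and per Mb of H3K4me3 the rise was from 38.7 to 65.5 summits. Of the siMITF peaks, 10.6% (2586 of 24431) did. Up to 4 summits lay in a single siSCR peak, as on chromosome 17 at 7474632 to 7488699 and at 8088607 to 8094139, and on chromosome 19 at 1166333 to 1174711.

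The MAX peaks of highest fold lay mostly in regions marked in both arms. These were on chromosome 17 at 57642626 to 57643120 (fold 34.0, 109 reads at the summit), chromosome 5 at 170815408 to 170815755 (fold 29.0, 64 reads), chromosome 12 at 109531028 to 109531399 (fold 26.8, 48 reads) and chromosome 19 at 50529179 to 50529611 (fold 25.8, 39 reads). The fifth, on chromosome 8 at 2129694 to 2130393 (fold 24.9, 36 reads), lay outside both H3K4me3 lists. Outside both lists it was followed by chromosome 2 at 68589173 to 68589465 (fold 22.6), chromosome 12 at 24187184 to 24187471 (fold 21.4), chromosome 2 at 11919297 to 11919599 (fold 20.5) and chromosome 14 at 65150057 to 65150445 (fold 18.0).

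The share of MAX summits inside siSCR H3K4me3 rose with the read pileup at the summit, which had a median of 12 reads (range 5 to 290). It was 15.7% of the 611 summits with 5 to 7 reads, 45.9% of the 1547 with 10 to 12 reads and 79.6% of the 764 with 20 to 29 reads. Summits with 20 or more reads, a limit set after the values were seen, had shares of 79.1% (76.6 to 81.4) in siSCR and 75.6% (73.0 to 78.0) in siMITF. Local background rose with pileup, and among summits with background under 2 times the genome-wide floor the share inside siSCR was 18.8% (17.1 to 20.7) at under 10 reads and 48.0% (41.0 to 55.1) at 16 or more reads. By fold there was no such rise: the share was 60.3% (57.5 to 63.0) in the lowest quintile, between 44.1% and 45.2% in the next 3, and 56.1% (53.4 to 58.9) in the highest. MAX and H3K4me3 were mapped in different cells, and H3K4me3 of COL0829 was not analysed here.

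**Figure D3:**
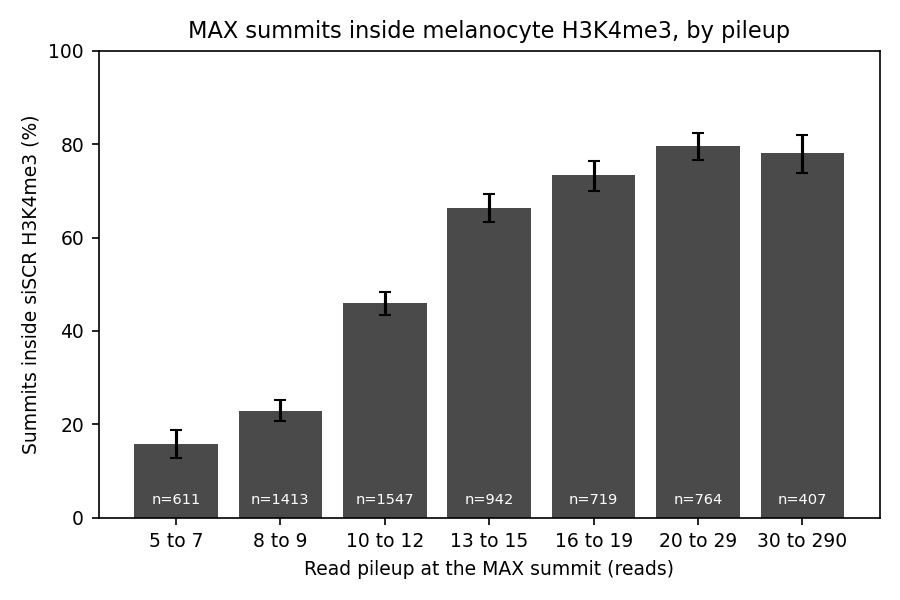
Percent of COL0829 MAX summits inside siSCR melanocyte H3K4me3 peaks (y axis) by the read pileup at the summit (x axis), with the number of summits in each bar and exact 95% intervals for counting error. The share climbs from 15.7% at 5 to 7 reads to 79.6% at 20 to 29 reads and is 78.1% at 30 to 290 reads.

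The last comparison between the arms asked whether H3K4me3 regions bound by MAX in the melanoma line kept their mark after MITF siRNA more often than other regions. Of the 2892 siSCR peaks with a MAX summit, 92.7% (91.7 to 93.6) had a siMITF peak, against 67.1% (66.5 to 67.6) of the 30780 without, a difference of 25.6 percentage points (24.5 to 26.6, Newcombe interval). Peaks with MAX were also stronger and wider, with a median fold of 15.2 against 5.61 and a median width of 2614 bp against 1107 bp. In the lowest quintile of fold, 37.4% (29.8 to 45.5) of peaks with MAX and 19.8% (18.8 to 20.7) of those without had a siMITF peak. In quintile 2 the shares were 59.6% (52.2 to 66.7) and 39.2% (38.0 to 40.4), in quintile 3 they were 89.2% and 86.4%, and in the highest quintile 100% and 99.98%. Averaged over quintiles of fold or of width, weighted by the peaks with MAX, the difference was 2.69 or 2.86 percentage points, and over 30 strata of fold and width, chosen after the values were seen, it was 1.52. Of the 2892 peaks with MAX, 2187 lay in fold quintiles 4 and 5, where nearly all peaks were shared. Over fold quintiles 1 to 3, also chosen after the values were seen, the difference was 10.8, with width left out of account. By quintile of width, from lowest to highest, the differences were 5.87, 3.44, 7.83, 3.48 and 0.838 percentage points.

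MAX peaks were spread unevenly over the autosomes relative to H3K4me3. Chromosome 22 had 38.3 MAX peaks per 100 siSCR H3K4me3 peaks, chromosome 20 had 32.1, chromosome 7 had 27.3 and chromosome 3 had 25.4. Chromosomes 13 and 18 had 7.52 and 7.58, and chromosome 4 had 8.91. A MAX summit lay in 13.8% (11.3 to 16.6) of siSCR peaks on chromosome 22 and in 3.64% (2.47 to 5.16) on chromosome 13. Counting only summits outside both H3K4me3 lists, the rate per 100 siSCR peaks ran from 2.92 on chromosome 18 to 22.2 on chromosome 22. On chromosome 22, 7.19% of these outside summits had a local background at the genome-wide minimum, against 58.1% on chromosome 13.

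**Figure D4:**
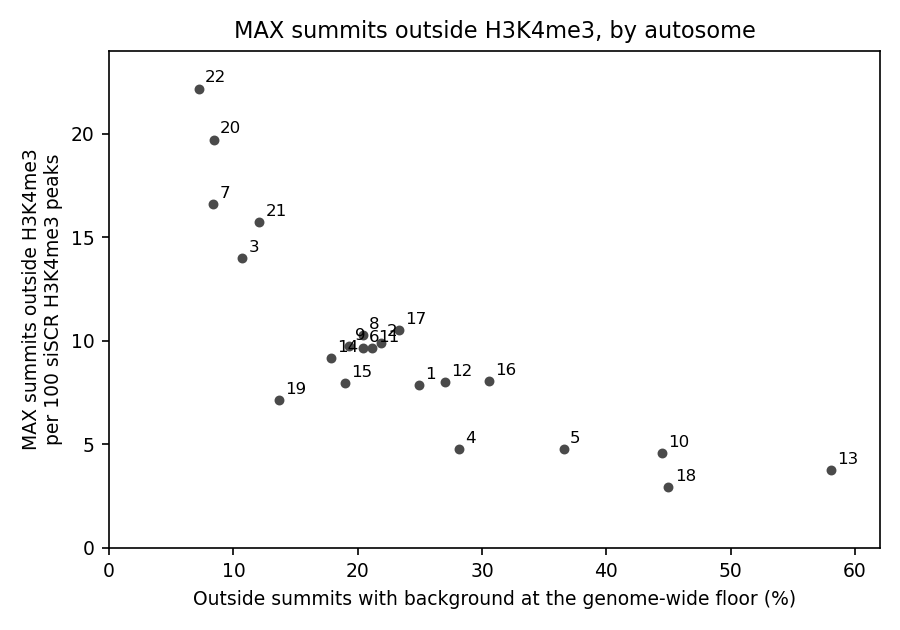
MAX summits outside both H3K4me3 lists per 100 siSCR H3K4me3 peaks (y axis) against the percent of those summits whose local background is at the genome-wide floor (x axis), 1 point per autosome, labelled by chromosome number. The count of outside summits enters both axes, so a falling trend is in part built in. Chromosomes 22 and 20 sit highest, at 22.2 and 19.7, with 7.19% and 8.43% at the floor; chromosomes 13 and 18 sit lowest, at 3.76 and 2.92, with 58.1% and 45.0% at the floor.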

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

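Alternatives chosen after the data were seen were the 30 strata, fold quintiles 1 to 3, the limits of 20 reads and of 10 times the floor, the −log10 q of 20, the 1 kb distance and the stricter lists for summit position. The difference between siSCR peaks with and without MAX kept its direction under each alternative run. The stratified differences have no interval, and fold and width still varied within strata. The kept direction therefore does not show a difference beyond peak strength and width. The other values are shares or counts, which cannot reverse. Of all alternatives, 26 moved beyond their counting error, or beyond a fixed ratio for counts of peaks, and 8 did not. The cause of a move was not tested unless the alternative's construction gives it. With at least 50% of a peak covered, 62.8% of siSCR and 93.7% of siMITF peaks were shared. At −log10 q of at least 5 these were 73.8% and 99.3%, and with equal numbers of top peaks 87.6% and 88.5%, which lists of equal length bring close together by construction. Shared siSCR bases came to 76.5% at −log10 q of at least 5, 81.0% with equal numbers and 74.6% after merging, a move that passed its counting error only because bases were counted singly. The gap between siSCR peaks with and without MAX was 27.8 percentage points at 50% coverage, 18.4 with the H3K4me3 lists at −log10 q of at least 5, 2.86 over width quintiles, 2.69 over fold quintiles, 10.8 over fold quintiles 1 to 3 and 1.52 over 30 strata. MAX in siSCR and siMITF H3K4me3 was 51.9% and 46.4% by whole peaks, 46.7% and 41.2% with stricter H3K4me3, 57.9% and 51.9% with stricter MAX peaks, 48.5% and 43.0% with background under 10 times the floor, and 79.1% and 75.6% with 20 or more reads. The planned results at transcription start sites, E-boxes and gene lists were not run. No paired analysis was possible because each ChIP-seq arm had 1 library and the RNA-seq samples, whose labels share replicate numbers, were not analysed here.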

Other observations

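The tests below were chosen after the result was seen, except the floor share over 10 Mb windows within chromosomes and the comparison of pileups at low background. The bound that set aside the edge of H3K4me3 peaks was moved from 10% to 50% after its value was seen, and a second condition was added to the test of strong siSCR peaks after its count was seen.

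H3K4me3 regions present in both arms were often covered only in part by siMITF peaks. Shared siSCR peaks were covered over a median of 88.0% of their width (interquartile range 74.0 to 96.2), while shared siMITF peaks were covered over a median of 100% (94.4 to 100). Among the 16733 shared siSCR peaks at or above the list's median −log10 q, 424 were covered over less than 50% of their width. The smallest covered shares were 7.16% on chromosome 14 at 34632642 to 34638944, 7.62% on chromosome 12 at 109195517 to 109198772 and 8.09% on chromosome 7 at 2691622 to 2698851, which contained a MAX summit. The implied background of siMITF was 0.494 times that of siSCR, and whether this accounts for the partial cover was not tested.

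MAX summits outside both H3K4me3 lists lay nearer to H3K4me3 than shifted positions did. Within 5 kb of a peak lay 24.1% (22.6 to 25.7) of the 3132 summits, against a mean of 13.4% for shifted positions, and within 50 kb lay 79.2% (77.8 to 80.6) against 54.7%. The median distance was 16.2 kb. The highest local background was at a MAX peak on chromosome 1, 121484515 to 121484820, with 290 reads over a background of 178 and a fold of 1.62.

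Most siSCR peaks without a siMITF peak may reflect a shallower siMITF library. The background implied over shared wide peaks was 0.494 times that of siSCR, and the lost peaks were weak. The median pileup solved over the same peaks was 0.461 times that of siSCR. Read totals and the input libraries were not analysed, so these ratios alone do not establish a lower depth. For the 39 lost siSCR peaks with a −log10 q of at least 20 lower depth stays open: 79 shared peaks of that strength had a best siMITF −log10 q under 3, which a graded loss of the mark would give as well. Over shared peaks with a siSCR −log10 q of 50 or more, where 4 were lost, the median best siMITF −log10 q was 38.2 and the 1st percentile 14.4, while 4 of those shared peaks were under 3. A loss of H3K4me3 after MITF siRNA stays open as the biological candidate, with the depletion of MITF itself not checked. It cannot be told apart from a difference between the single cultures, libraries or lanes, since there was 1 library per arm.

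The uneven spread of MAX peaks over chromosomes may follow the copy number of the chromosomes in COL0829. Over 22 autosomes, which are not independent replicates, the rate of MAX summits outside H3K4me3 fell as the share with background at the floor rose. The Spearman rho was −0.805, and −0.741 without chromosomes 13 and 18. The outside summits are the numerator of the rate and the denominator of the floor share, which favours a negative rho. Against the share of siSCR peaks with MAX, which lacks that shared count, the floor share had a rho of −0.593. With the median background the rate had a rho of 0.621. Many autosomes had a median background of 0.746 reads, so this rho hardly orders them. Within chromosomes, over 193 windows of 10 Mb, rho was −0.186 for the floor share and 0.251 for the median background, but windows were kept only with at least 5 outside summits, which removes windows of low rate, so these values decide nothing and copy number within chromosomes stays open. Density of H3K4me3 peaks, as a stand-in for promoters, gave a rho of 0.261 and also stays open. No biological explanation was tested.

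MAX summits outside melanocyte H3K4me3 could in part be weak peaks near the calling threshold. The share inside siSCR H3K4me3 was 60.7 percentage points higher in the top than in the bottom quintile by pileup. Background rose with pileup, so pileup alone does not measure closeness to the threshold. Among summits with background under 2 times the floor, the share was 29.2 points higher at 16 or more reads than at under 10. By the peaks' own −log10 q the contrast was smaller: 57.9% at 5 or more, against 50.1% of all MAX peaks. The tables argue against regions of very high background, which held 2.36% of the outside summits, and against summits just beyond a peak edge as the whole account, since 347 (11.1%) lay within 1 kb. Of the 234 outside summits with 20 or more reads, 72 lay at background above 10 times the floor, weak peaks leave out the other 162, and the share inside did not rise steadily with fold. MAX binding at sites marked in COL0829 but not in melanocytes stays open and was not tested.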
